A study of Homo sapiens with 6 samples.

How the data were processed

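Total RNA from 6 samples of the glioblastoma cell line U87 was measured, 3 labelled as the empty vector control and 3 labelled as MGMT-transfected. Per the labels, Cy3-labelled cRNA was made from 0.5 ug of RNA per sample, and the series design text calls the control line parental while the sample labels call it an empty vector control. Each sample was hybridized to 1 array, and none was pooled.

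The deposited scanner files hold the fluorescence intensity of each spot in arbitrary units. Per the file headers they were made with Agilent Feature Extraction 9.5.3.1, while the submitters' notes name version 9.1. Its processed signal is an intensity from which the local background trend was subtracted, with surrogate values for signals near the background, and it is not scaled between arrays. The deposited files also hold the mean intensity of each spot and the median intensity of its local background, and flags for spots well above background, saturated or uneven. The authors' processed table holds log2 values. Compared with the scanner files over 41000 matched probes, these were log2 signals scaled to the 75th percentile of each array and then centred on each probe's median over the 6 arrays (correlation across probes 0.9989 to 0.9998 per array).

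The processed signal of each spot was taken as log2 minus the 75th percentile of its array, and this is called the relative level. Control spots and spots marked as outliers were left out (63 to 101 per array), and 43376 spots were not controls. Spots of 1 probe were averaged, which concerned 264 probes printed 10 times. A probe was tested if it was well above background on all 3 arrays of at least 1 group (for repeated probes, in at least 0.5 of the spots), and the probe with the highest mean stood for its gene. Signals at or under 0 were set to the smallest positive signal of the array. Positions are those of the files on hg17. Current gene symbols came from a RefSeq gene table of assembly GRCh38.p14, used for names only: 23434 probes matched by accession, 2317 by symbol and 1043 by synonym, and 14206 kept the name in the files. The 41000 probes carried 30990 names. No annotation of hg17 was at hand, so exons, introns and untranslated regions are not given.

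The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with data.table version 1.17.8, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. The threshold was an adjusted p under 0.05. Differences are log2, labelled MGMT minus labelled empty vector, with the standard error (SE) from limma and 3 samples per group. Every named gene past the threshold had all 3 libraries of one group beyond all 3 of the other. Where no array of a group was well above background, the fitted difference depends on values at the floor. The fold was then computed from the mean of the bright group and a floor, the mean over the arrays of the dim group of the lowest relative level that counted as well above background, and is given as "at least". A difference also depends on values near the floor where 1 or 2 arrays of a group were well above background. No such bound is given where another probe of the gene was above background in the dim group.

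Gene lists were tested with camera (preset correlation 0.01, two-sided, adjusted over the 30 lists with at least 5 tested members). The same test was run with an estimated correlation, and fry beside it. Members were also counted after adjustment over the list alone. List medians were recomputed with genes at the floor of 1 group set to their bound, and none changed. The lists were written from general knowledge of glioblastoma, angiogenesis, the targets of sunitinib, matrix, DNA repair and cell stress, with markers of other cell types. The comparison, the lists, the alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise.

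The rule named MGMT; the 12 largest rises and 12 largest falls among genes with a symbol that passed the threshold, had separate groups and were well above background and not saturated on all 3 arrays of the higher group; every tested receptor kinase and VEGF or PDGF ligand; up to 4 members of each other list with the largest differences past the threshold; and ANGPT1, ANGPT2 and TEK. It gave 140 genes, and none had another probe that moved the opposite way by over 2-fold. Of these, 3 genes are not reported here, and the counts include them.

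The slide of each array was read from the files. It was used as a block and, for the 1 slide that held both groups, the comparison was repeated within it. Replicate numbers were checked as possible pairs: the deviations of replicates 1, 2 and 3 from their group means had correlations of 0.271, 0.155 and 0.213 across genes between the groups, so the replicate number was also tried as a block. The spread between any 2 replicates was 4.08 to 33 times the noise between repeated spots over 200 probes, a noise that leaves out labelling and hybridization, so the ratio does not tell whether the samples were separate cultures. Empty vector replicate 1 differed by more than 2-fold from the mean of replicates 2 and 3 in 5664 genes, against 374 between replicates 2 and 3.

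Alternatives were normexp background correction (offset 50), quantile normalization, no scaling, median scaling, no filter, a filter on all 6 arrays, the mean over the probes of a gene, each probe on its own, the authors' processed values, eBayes with trend and robust settings, the replicate block, the slide block, a threshold of 0.01, the methods' test with Bonferroni correction, and leaving out each replicate. Spike-in scaling and the slide as a random block were added after the data were seen. The fit was tested on simulated data with 21501 genes, where it recovered 10% of the genes changed 2-fold, 64% at 4-fold, 70% at 8-fold and 84% at 16-fold, of 50 genes each, and called 8 unchanged genes. It called the 1 list that was shifted and none that was not. Each simulated gene was drawn on its own, so the simulation does not cover lists whose genes move together. In the data the estimated correlation of the G2 and mitosis list was 0.993. Few simulated genes were changed, so the recovered shares do not carry over to data in which 8735 genes passed. Terms of the gene ontology were not tested, since no annotation of them was at hand.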

Results

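Gene expression was measured in U87, an established human glioblastoma cell line, on 6 single-colour oligonucleotide arrays. The labels give 3 samples as the empty vector control and 3 samples as transfected with MGMT, the gene of a DNA repair enzyme that removes alkyl groups from guanine. The series title names angiogenesis and the receptor kinase inhibitor sunitinib as the subject, and no label gives a drug treatment. Between 68.8% and 70.8% of the 41000 probes were well above background on each array. The 75th percentile of the probe signal was 778, 649 and 641 for empty vector replicates 1, 2 and 3 and 686, 808 and 655 for MGMT replicates 1, 2 and 3. The number of arrays limits the precision. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples. The 3 empty vector arrays and MGMT replicate 3 lay on 1 slide, and MGMT replicates 1 and 2 lay on the other, which held no empty vector array.

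The comparison of the 2 groups asks how gene expression differed between MGMT-transfected and control U87 cells, and MGMT itself was read first. MGMT was bright in all 3 libraries labelled empty vector and at background in all 3 libraries labelled MGMT, which is the opposite of the labels. Its signal was 910.1 ± 81.3 (SD, n = 3) in the libraries labelled empty vector and 1.43 ± 0.290 (SD, n = 3) in those labelled MGMT. The array held 1 MGMT probe (A_23_P104323, chromosome 10, 131396272 to 131447489 on hg17, sequence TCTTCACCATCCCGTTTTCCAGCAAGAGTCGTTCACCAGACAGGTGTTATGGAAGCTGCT). The log2 difference, labelled MGMT minus labelled empty vector, was -9.39 (SE 0.262, limma adjusted p = 3.35e-06). Since no library labelled MGMT was above background, this was a fall of at least 190-fold (189.8). On the slide that held both groups the difference was -8.96. The exact two-sided permutation test of the 6 values gave p = 0.1, the smallest p that 3 samples against 3 allow. Groups are therefore named by their labels throughout, and "higher" and "lower" mean higher and lower in the libraries labelled MGMT. If the labels of the 2 groups were exchanged, every direction would turn.

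**Figure D1:**
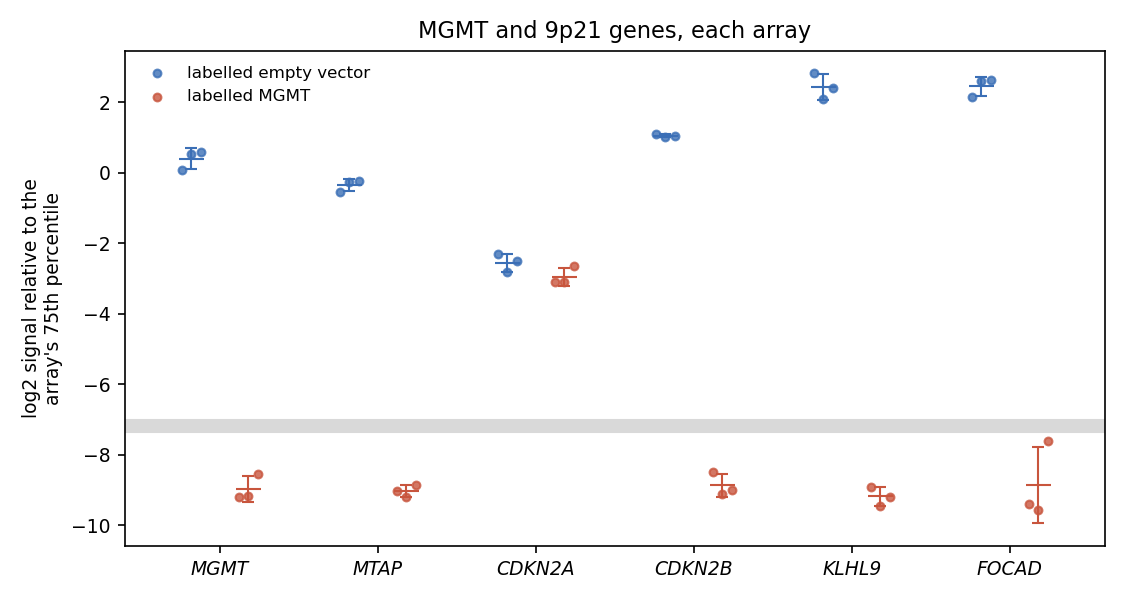
Level of MGMT and of 5 genes of 9p21 on each array (y axis, log2 signal relative to the array's 75th percentile), with points for single arrays, horizontal lines for the mean and bars for the SD of 3 arrays, and a grey band where signals stopped being well above background. MGMT, MTAP, CDKN2B and the plotted probes of KLHL9 and FOCAD were bright in the libraries labelled empty vector and at background in those labelled MGMT. The plotted probe of CDKN2A was above background in both.

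The 2 groups differed broadly. Of 21501 genes tested with limma, 4376 were higher and 4359 lower, together 8735 or 40.6%, and 6779 of them differed by more than 2-fold (3336 higher and 3443 lower). A further count at 10-fold gave 1826 genes. All 3 libraries of one group lay beyond all 3 of the other for 12106 genes (56.3%), where chance gives 10%. A total of 733 genes were well above background on every array labelled empty vector and on none labelled MGMT, and 636 genes showed the reverse. Correlation across probes was 0.967 to 0.993 between arrays labelled empty vector, 0.986 to 0.992 between arrays labelled MGMT and 0.912 to 0.919 between the groups, where probes are not independent replicates. With the slide as a block, which leaves the comparison within 1 slide, 3923 genes passed, and 3871 of the 6779 genes were among them. Without MGMT replicate 2, 5643 genes passed. The share of higher genes among those past the threshold was 50.1% when arrays were scaled to their 75th percentile and 32.4% when they were scaled to their spike-in probes, a scaling chosen after the data were seen that moved the median of all genes from 0.05 to -0.28.

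The largest fitted rise was that of ARSI, an arylsulfatase (chromosome 5, 149656843 to 149656902 on hg17), with a log2 difference of 12.79 (SE 0.306, adjusted p = 2.62e-06), at least 1894-fold. EREG, a ligand of the epidermal growth factor receptor, was at least 497-fold higher (SE 0.193 on the log2 scale, adjusted p = 2.40e-06). NETO2, an auxiliary subunit of kainate receptors, was at least 656-fold higher. Other large rises were at least 498-fold for HAS1 (hyaluronan synthase), 465-fold for LXN (a carboxypeptidase inhibitor), 431-fold for BLK (a Src family kinase), 379-fold for SNURF (an imprinted gene), 375-fold for IGFBP1 (an insulin-like growth factor binding protein) and 261-fold for TMPRSS15 (enteropeptidase). ANKRD35, above background in 1 library labelled empty vector, was higher by 10.07 on the log2 scale.

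The largest fitted fall was that of IGFBP5, another insulin-like growth factor binding protein (chromosome 2, 217362673 to 217362732 on hg17), at -12.10 (SE 0.484, adjusted p = 1.17e-05). It was above background in 1 library labelled MGMT, and falls to or near the background cannot be ranked by size. GSTM3, a glutathione transferase above background in 2 libraries labelled MGMT, differed by -11.54 (SE 0.194, adjusted p = 2.40e-06) and COL18A1, the collagen from which endostatin is cut, by -11.10 (SE 0.194, adjusted p = 2.40e-06). KLHL9, an adaptor of a cullin ubiquitin ligase, was at least 778-fold lower (log2 difference -11.62, SE 0.259, adjusted p = 2.58e-06) on the probe tested. The other probe of KLHL9 was at background in both groups. DTNBP1, which encodes dysbindin, was at least 756-fold lower, with a fall on its other probe too (-6.00). FOCAD, which encodes focadhesin, differed by -11.31 on 1 probe and by -2.57 on another that was above background in all 6 libraries. The other large falls were at least 575-fold for FOXF2 (a forkhead transcription factor), 506-fold for CMTM8, 494-fold for GLDN (gliomedin), 489-fold for NPTX1 (neuronal pentraxin), 391-fold for FGG (fibrinogen gamma chain) and 358-fold for RFLNB (refilin B). FGG was lower by 5.82 in empty vector replicate 1 than in replicates 2 and 3. Of the 131 genes past the threshold among those the rule named, 111 passed with the slide as a block and 20 did not. Of those given here, NRP1, PGF, ANGPT2, SPP1, CDH6, ATR, DDB2, CCNE1, SLBP, MKI67, PECAM1, HLA-DRA and LUM did not. Empty vector replicate 1 differed from the mean of replicates 2 and 3 by over 2 on the log2 scale in 17 of the genes given here. It was the higher for CXCL1, EFNB2 and SPP1, and the lower for FGG, PDGFRA, ANGPT1, TEK, SEMA3A, ITGA8, CDH6, MMP13, MKI67, ALDH3A1, PECAM1, HLA-DRA, LAPTM5 and LUM.

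KLHL9 and FOCAD lie on 9p21, and the neighbours given here were chosen after their values were seen. MTAP, a methionine salvage enzyme (chromosome 9, 21827969 to 21844648 on hg17), was above background in the 3 libraries labelled empty vector and in none of the 3 labelled MGMT, on each of its 3 probes. Its log2 difference was -8.68 (SE 0.187, adjusted p = 2.51e-06), at least 113-fold. CDKN2B, a cyclin-dependent kinase inhibitor, was at least 296-fold lower (-9.92, SE 0.214, adjusted p = 2.51e-06). MLLT3, a component of the super elongation complex, was at least 28.5-fold lower (-6.92), and DMRTA1 at least 8.91-fold lower (-4.24). CDKN2A, which lies between MTAP and CDKN2B, was above background in all 6 libraries, with relative levels of -2.55 and -2.95 and an adjusted p of 0.20 on 1 probe, and its other probe was at background in both groups. RPS6, a ribosomal protein gene outside this stretch, was above background in all 6 libraries too (difference 0.07, adjusted p = 0.814). Other genes outside it did differ. PLIN2, above background in 1 library labelled MGMT, differed by -8.17 (SE 0.491, adjusted p = 5.85e-05). The entry BC037528 was at least 33.1-fold higher (6.86, SE 0.173, adjusted p = 2.72e-06).

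**Figure D2:**
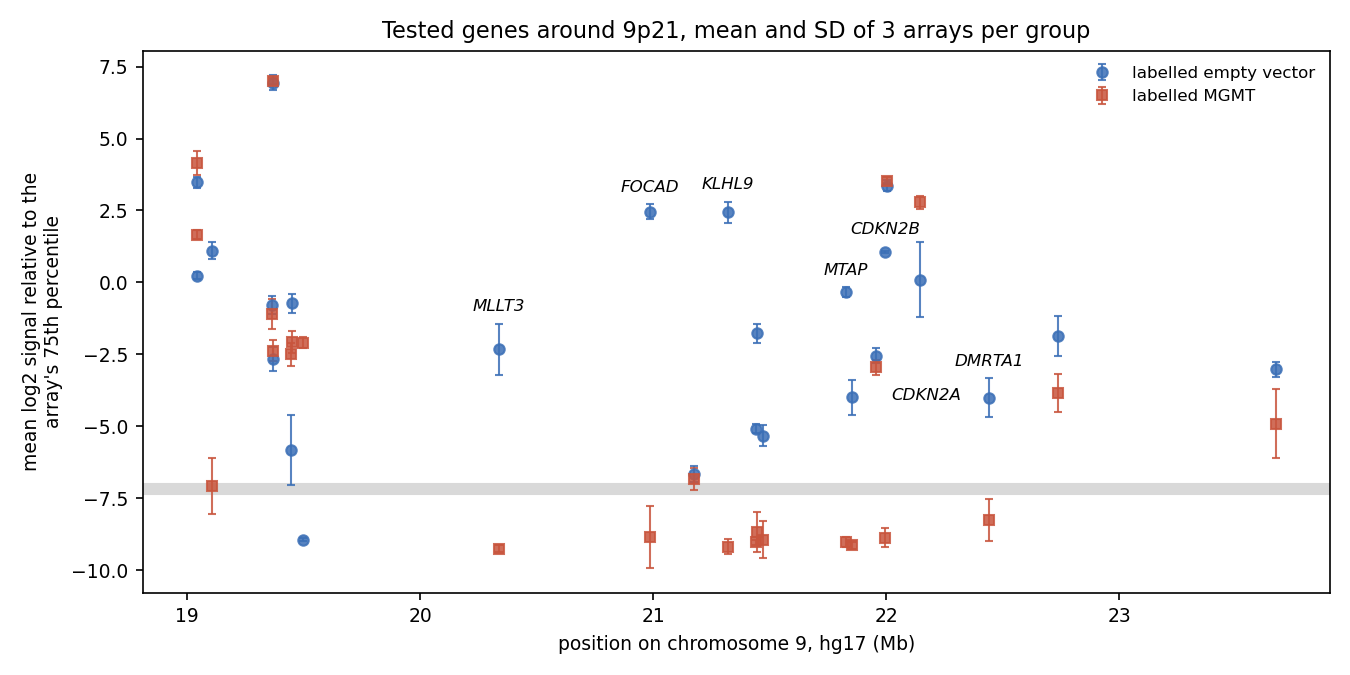
Tested genes between 19.0 and 24 Mb of chromosome 9 (x axis, hg17 position in Mb) with their mean level in each group (y axis, log2 signal relative to the array's 75th percentile), bars for the SD of 3 arrays and a grey band where signals stopped being well above background. Between MLLT3 and DMRTA1 most genes were at background in the libraries labelled MGMT, while CDKN2A, IFNA4 and 2 unnamed probes next to CDKN2B were above background in both groups.

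Among the receptor kinases that sunitinib inhibits, 2 were higher, 2 lower and 3 not past the threshold of the 7 tested, and 4 passed when adjusted over the list alone. CSF1R, the receptor of colony stimulating factor, was higher by 7.94 (SE 0.441, adjusted p = 4.29e-05). KDR, the main VEGF receptor of endothelium, was higher by at least 4.62-fold (4.03, SE 0.241, adjusted p = 5.78e-05) on the probe tested, and its other probe was at background in both groups. KIT, the stem cell factor receptor, was lower by at least 3.80-fold (-3.29, SE 0.250, adjusted p = 0.000156). FLT1, a VEGF receptor, was lower by at least 2.53-fold (-3.67, SE 0.414, adjusted p = 0.000886), and its level was higher by 1.43 in empty vector replicate 1 than in replicates 2 and 3. The other probe of FLT1 was at background in both groups. With normexp background correction KDR and KIT did not pass (0.38 and -0.44), and FLT1 passed at -0.46. PDGFRB differed by -0.19 (SE 0.167, adjusted p = 0.399) and FLT4 by -0.06 (SE 0.226, adjusted p = 0.862). PDGFRA differed by -1.71 (SE 1.20, adjusted p = 0.295) and, without empty vector replicate 1, by -3.19 with an adjusted p of 0.000194, the lowest of its alternatives, whose highest was 1. FLT3 and RET were at background and were not tested. Camera, which compares a list with all other genes, did not call the list (adjusted p = 0.897). By fry, which tests the list without the other genes, it passed (adjusted p = 0.0282). In both tests moves in opposite directions cancel.

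The VEGF and PDGF ligands and coreceptors held 4 higher, 3 lower and 4 not past of 11 tested, and 8 passed when adjusted over the list alone (camera adjusted p = 0.941). VEGFA, the main angiogenic ligand, was higher by 2.41 (SE 0.279, adjusted p = 0.000991) and its coreceptor NRP2 by 3.63 (SE 0.418, adjusted p = 0.000977). NRP1, the other coreceptor, was higher by 2.02 (SE 0.437, adjusted p = 0.0124), and PGF, placental growth factor, by 1.84 (SE 0.435, adjusted p = 0.0170). Neither passed with the slide as a block (adjusted p = 0.124 and 0.0603, with alternatives for NRP1 from 0.000529 to 1). Without MGMT replicate 2 or 3 PGF did not pass either (adjusted p = 0.0653 and 0.0604, over a range of 0.00283 to 1 for its alternatives). PDGFD was lower by at least 158-fold (-8.93, SE 0.237, adjusted p = 2.99e-06) and VEGFD by at least 3.67-fold (-1.90, SE 0.256, adjusted p = 0.00189, but -0.35 and adjusted p = 0.0917 with normexp background correction), and PDGFB, above background in 2 libraries labelled MGMT, differed by -3.18 (SE 0.417, adjusted p = 0.00167). PDGFA (-0.68), VEGFB (-0.67), PDGFC (0.62) and VEGFC (1.48) did not pass, with adjusted p of 0.181, 0.192, 0.122 and 0.0699. VEGFB and VEGFC passed with the replicate number as a block (adjusted p = 0.0397 for each), and VEGFC also with the slide as a random block and, at 2.11, without empty vector replicate 1. ANGPT2, the angiopoietin that antagonises TEK signalling, was higher by at least 4.39-fold (3.55, SE 0.560, adjusted p = 0.00356) on the probe tested, and its other probe was at background in both groups. It did not pass with normexp background correction (0.41, adjusted p = 0.159) or with the slide as a block (adjusted p = 0.0573, over a range of 0.00086 to 1 for its alternatives). ANGPT1 differed by 0.90 (SE 1.19, adjusted p = 0.578) and their receptor TEK by 2.30 (SE 1.15, adjusted p = 0.157), and in both genes empty vector replicate 1 lay below the other replicates by over 4 on the log2 scale. Without it TEK passed, at 0.89, and ANGPT1 did not, at -0.56.

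**Figure D3:**
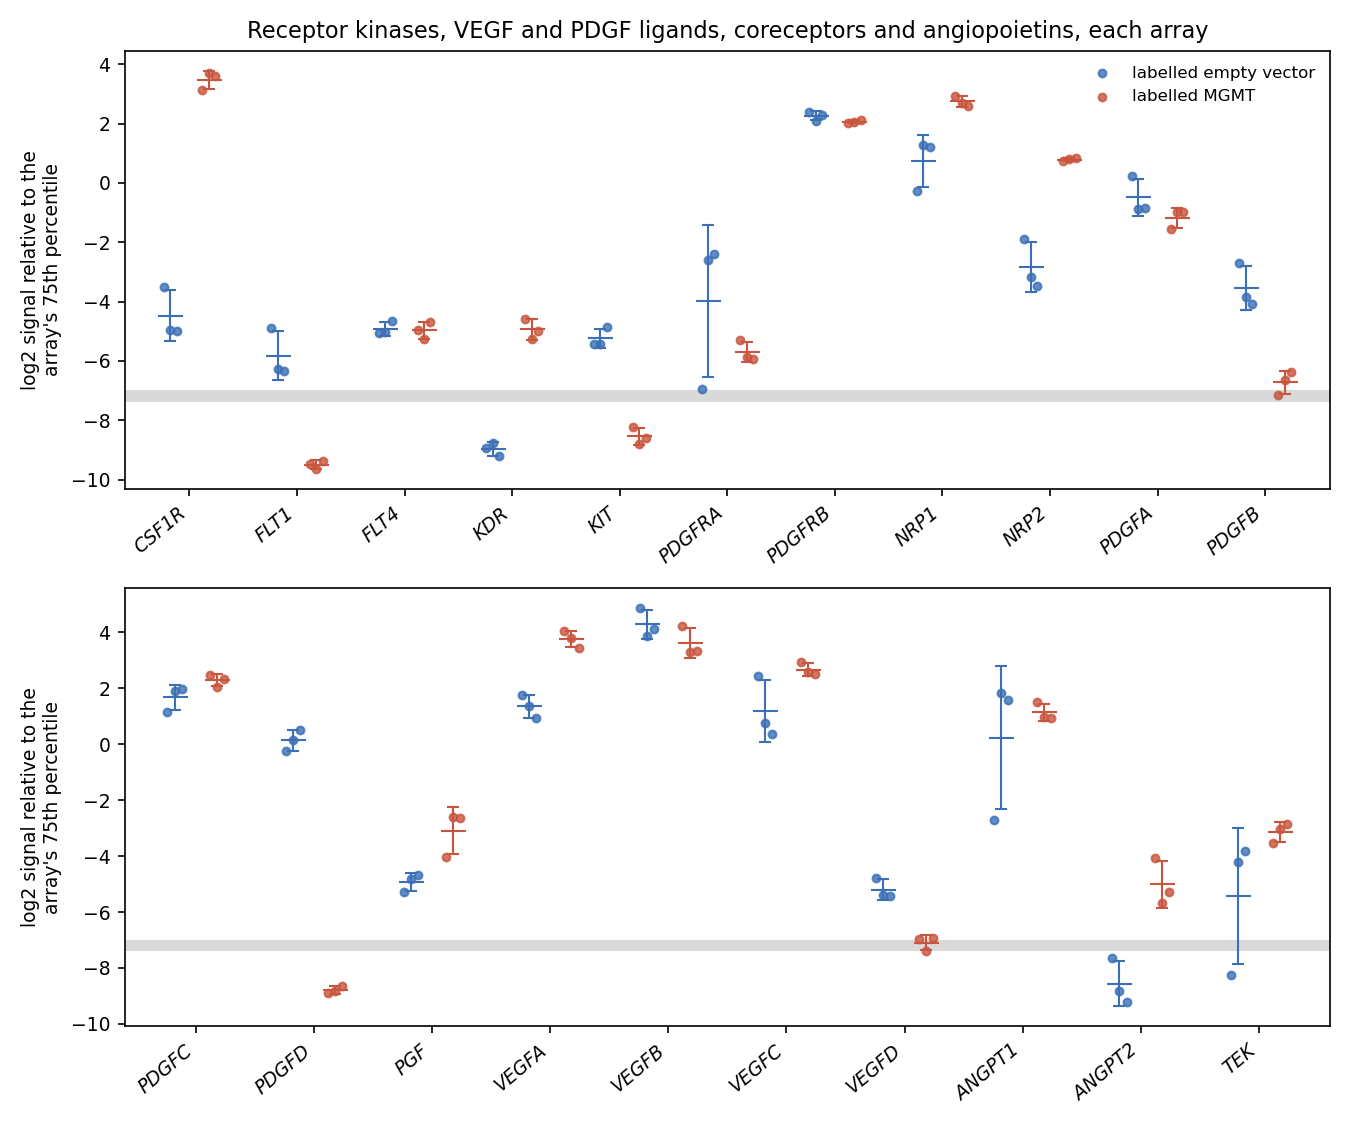
Level of the receptor kinases, VEGF and PDGF ligands, coreceptors and angiopoietins on each array (y axis, log2 signal relative to the array's 75th percentile), with points for single arrays, horizontal lines for the mean and bars for the SD of 3 arrays, and a grey band where signals stopped being well above background. CSF1R, NRP2 and VEGFA were higher and PDGFD lower in the libraries labelled MGMT, and empty vector replicate 1 stood apart for PDGFRA, ANGPT1 and TEK.

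Other pro-angiogenic factors moved in both directions. Of 34 tested, 13 were higher, 10 lower and 11 not past, and 26 passed when adjusted over the list alone (camera adjusted p = 0.425). Besides EREG, the chemokine CXCL1 (7.33, SE 0.841, adjusted p = 0.000955) and the ephrin EFNB2 (7.19, SE 0.976, adjusted p = 0.00192) were higher, though CXCL1 was above background in 1 library labelled empty vector, replicate 1, and MDK, the heparin-binding factor midkine, was lower (-7.27, SE 0.228, adjusted p = 5.37e-06). The endogenous angiogenesis inhibitors held 7 higher, 8 lower and 4 not past of 19, and 17 passed when adjusted over the list alone (camera adjusted p = 0.558). COL18A1 was lower, as given above, and so was the semaphorin SEMA3A (-5.61, SE 0.593), while TIMP1, given below, was higher.

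Genes of the hypoxia response were mostly higher. Of the 30 tested, 20 were higher, none was lower and 10 were not past, and 21 passed when adjusted over the list alone. The median log2 difference was 1.01, and 0.88 within the slide that held both groups (camera adjusted p = 1.75e-05, and adjusted p = 0.329 with an estimated correlation). CA9, a carbonic anhydrase, was higher by 9.48 (SE 0.476, adjusted p = 2.84e-05), the glycolytic enzyme ALDOC by 7.26 (SE 0.337, adjusted p = 2.09e-05) and PFKFB4, a regulator of glycolysis, by 4.71 (SE 0.158, adjusted p = 6.51e-06).

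Matrix proteases and the plasminogen system were mostly higher, with 18 higher, 6 lower and 9 not past of 33 tested, and 26 passed when adjusted over the list alone. The median was 1.79, and 1.68 within the slide (camera adjusted p = 0.0210, and adjusted p = 0.329 with an estimated correlation). Without empty vector replicate 1 the call was lost (adjusted p = 0.114, over a range of 0.000994 to 0.329 for the alternatives of the list). ADAM23, an integrin-binding member of the ADAM family, was at least 164-fold higher (8.86, SE 0.214). MMP13, a collagenase, was at least 130-fold lower (-9.28, SE 1.07, adjusted p = 0.000996), with a level lower by 3.96 in empty vector replicate 1 than in replicates 2 and 3. Collagens held 10 higher, 4 lower and 9 not past of 23, and 14 passed when adjusted over the list alone (camera adjusted p = 0.332). COL1A1, a chain of fibrillar collagen, was higher by 8.31 (SE 0.276, adjusted p = 6.31e-06), COL5A3 by at least 54.3-fold, and the basement membrane chain COL4A1 differed by -5.84 (SE 0.377, adjusted p = 8.09e-05).

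The other matrix proteins held 15 higher, 8 lower and 15 not past of 38, and 24 passed when adjusted over the list alone (camera adjusted p = 0.214). FBLN1, a fibulin, differed by -9.09 (SE 0.559, adjusted p = 6.49e-05), SPP1, which encodes osteopontin, by 7.57 (SE 1.39, adjusted p = 0.00651) and TNC, tenascin C, by 6.20 (SE 0.424, adjusted p = 0.000101). SPP1 did not pass with the slide as a block (adjusted p = 0.0788), and its difference was 9.27 without empty vector replicate 1, in which its level was higher than in replicates 2 and 3. Integrins held 6 higher, 7 lower and 5 not past of 18, and 16 passed when adjusted over the list alone (camera adjusted p = 0.740). The alpha chain gene ITGA7 was higher by 7.47 (SE 0.254, adjusted p = 6.93e-06), while ITGA8 was at least 41.4-fold lower and ITGA6 differed by -6.29 (SE 0.315, adjusted p = 2.81e-05). Of 22 cadherins and other adhesion molecules, 10 were higher, 7 lower and 5 not past, and 17 passed when adjusted over the list alone (camera adjusted p = 0.558). The protocadherins PCDH9 and PCDH17 were at least 46.2-fold and 91.8-fold higher, and the cadherin CDH6 was at least 98.4-fold lower, with a level lower by 4.61 in empty vector replicate 1 than in replicates 2 and 3.

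Genes of the unfolded protein and amino acid response were mostly lower, with 19 lower, 1 higher and 8 not past of 28 tested, and 20 passed when adjusted over the list alone. The median was -1.60, and -1.75 within the slide (camera adjusted p = 3.96e-07, and adjusted p = 0.329 with an estimated correlation). The transcription factors ATF3 (-4.75, SE 0.420, adjusted p = 0.000307) and DDIT3 (-3.78, SE 0.407, adjusted p = 0.000725) and the cystine transporter SLC7A11 (-4.67, SE 0.208, adjusted p = 1.78e-05) were lower. TRIB3, a pseudokinase of the same response, differed by -4.80 (SE 0.224), and since its signal was saturated on all 3 arrays labelled empty vector the fall was at least this large. Drug transporters and detoxification genes held 16 lower, 8 higher and 7 not past of 31, and 27 passed when adjusted over the list alone. Their median was -1.36, and -1.04 within the slide (camera adjusted p = 0.0405, and adjusted p = 0.465 with an estimated correlation). The aldehyde dehydrogenases ALDH3A1 and ALDH1A1 were at least 459-fold and 20.3-fold lower, where the level of ALDH3A1 was lower by 3.77 in empty vector replicate 1 than in replicates 2 and 3, and the aldo-keto reductase AKR1C1, saturated on 2 arrays labelled empty vector, differed by -5.91 (SE 0.399). The list call was lost without empty vector replicate 1 (adjusted p = 0.0857), without MGMT replicate 3 (adjusted p = 0.0535), with the replicate number as a block (adjusted p = 0.0517), with the filter on all 6 arrays (adjusted p = 0.138) and with spike-in scaling (adjusted p = 0.103), over a range of 0.0102 to 0.465 for its alternatives.

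Cholesterol synthesis genes held 9 lower, 1 higher and 11 not past of 21 tested, and 11 passed when adjusted over the list alone. Their median was -0.37, and -0.31 within the slide and -0.77 without empty vector replicate 1 (camera adjusted p = 0.0434, and adjusted p = 0.364 with an estimated correlation). DHCR7, which makes the last step to cholesterol, differed by -3.03 (SE 0.215, adjusted p = 0.000117), SC5D, a sterol desaturase, by -2.50 (SE 0.218, adjusted p = 0.000290) and HSD17B7, a sterol ketone reductase, by -2.35 (SE 0.189, adjusted p = 0.000205). The list call was lost without empty vector replicate 2, MGMT replicate 2 or MGMT replicate 3 (adjusted p = 0.0575, 0.0532 and 0.0709), with the replicate number as a block (adjusted p = 0.0517) and with the mean over the probes of a gene (adjusted p = 0.065, over a range of 0.0203 to 0.364 for its alternatives).

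Interferon-stimulated genes were more often lower than higher, with 19 lower, 2 higher and 15 not past of 36 tested, and 22 passed when adjusted over the list alone. The median was -1.39, and -1.53 within the slide (camera adjusted p = 6.62e-05, and adjusted p = 0.771 with an estimated correlation). BST2, the antiviral protein tetherin, differed by -6.99 (SE 0.388, adjusted p = 4.29e-05), the exonuclease ISG20 by -5.36 (SE 0.261, adjusted p = 2.56e-05) and the antiviral GTPase MX1 by -4.41 (SE 0.170, adjusted p = 1.00e-05). The median of the list was lower by 0.97 (-0.97) in empty vector replicate 1 than in replicates 2 and 3, and 27 members were lower without that replicate. Inflammatory cytokines and NF-kB targets held 12 lower, 8 higher and 10 not past of 30, and 23 passed when adjusted over the list alone (camera adjusted p = 0.448). CSF3, granulocyte colony stimulating factor, was at least 122-fold higher, IL11 was higher by 6.76 (SE 0.972, adjusted p = 0.00243) and BIRC3, an inhibitor of apoptosis, differed by -4.88 (SE 0.359, adjusted p = 0.000136).

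DNA repair genes, a list without MGMT, mostly did not pass, with 5 higher, 6 lower and 38 not past of 49 tested, and 7 passed when adjusted over the list alone (camera adjusted p = 0.713). Without empty vector replicate 1, 9 were higher and 14 lower. The helicase gene ERCC2 differed by -1.51 (SE 0.301, adjusted p = 0.00906), the damage kinase gene ATM by -1.40 (SE 0.242, adjusted p = 0.00515) and its relative ATR by 1.42 (SE 0.276, adjusted p = 0.00815). ATR did not pass with the slide as a block (adjusted p = 0.0627) or with spike-in scaling (1.09, adjusted p = 0.0714). Among p53 targets 12 were higher, 3 lower and 12 not past of 27, and 15 passed when adjusted over the list alone (camera adjusted p = 0.0546). CD82, a tetraspanin, was higher by 4.32 (SE 0.287, adjusted p = 9.04e-05), SESN1, a sestrin, by 2.58 (SE 0.163, adjusted p = 7.28e-05) and DDB2, a DNA damage sensor, by 2.48 (SE 0.438, adjusted p = 0.00562, and 0.0513 with the slide as a block). The p53 list passed in 6 of 20 alternatives, without empty vector replicate 3 or MGMT replicate 1 (adjusted p = 0.0443 and 0.0438), with normexp background correction (adjusted p = 0.0277), with no filter (adjusted p = 0.0252), with the filter on all 6 arrays (adjusted p = 0.0325) and with the slide as a block (adjusted p = 0.0498), over a range of 0.0252 to 0.364.

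Cell cycle genes were low in empty vector replicate 1. The median of the G2 and mitosis genes lay at -3.78 in that replicate relative to replicates 2 and 3, and that of the S phase genes at -2.75. Of 30 G2 and mitosis genes 1 was higher, none was lower and 29 were not past. By limma 0 passed when adjusted over the list alone and 4 passed unadjusted. Their median difference was 1.96, and 2.25 within the slide (camera adjusted p = 0.0195, and adjusted p = 0.854 with an estimated correlation). Without empty vector replicate 1 the median was 0.67, with 12 genes higher. The higher gene was MKI67, the proliferation marker (3.70, SE 0.945, adjusted p = 0.0226), whose call was lost without MGMT replicate 1, 2 or 3 (adjusted p = 0.0564, 0.0776 and 0.0704, over a range of 0.00107 to 1 for its alternatives). Of 25 S phase genes 2 were higher and 23 not past (camera adjusted p = 0.0570), and 0 passed when adjusted over the list alone, against 6 unadjusted. The 2 higher genes were CCNE1, cyclin E (1.87, SE 0.530, adjusted p = 0.0327), and SLBP, the histone stem-loop binding protein (0.99, SE 0.269, adjusted p = 0.0275). With 1 library left out, CCNE1 passed only without MGMT replicate 1, and SLBP did not pass without empty vector replicate 2 or 3 or MGMT replicate 2 or 3. The S phase list passed in 10 of 20 alternatives, with the replicate number as a block (adjusted p = 0.00147), the slide as a block, spike-in or no scaling, normexp background correction, no filter or the filter on all 6 arrays, and without empty vector replicate 2 or 3 or MGMT replicate 1 (adjusted p = 0.00758, 0.00862 and 0.0151). Without empty vector replicate 1 it did not (adjusted p = 0.669, over a range of 0.00147 to 0.877).

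Markers of glioma subtypes and neural lineages moved in both directions. Mesenchymal glioblastoma markers held 9 higher, 4 lower and 17 not past of 30, and 13 passed when adjusted over the list alone (camera adjusted p = 0.394). PDPN, podoplanin, was higher by 8.03 (SE 0.276, adjusted p = 7.20e-06) and TIMP1, a metalloproteinase inhibitor, by 3.73 (SE 0.481, adjusted p = 0.00157). Proneural and oligodendroglial markers held 3 higher, 5 lower and 8 not past of 16, and 8 passed when adjusted over the list alone (camera adjusted p = 0.713). The proteoglycan gene CSPG4 was at least 323-fold higher, and the transcription factor SOX11 differed by -8.79 (SE 1.08, adjusted p = 0.00125), and by -6.20 within the slide that held both groups, where MGMT replicate 3 was the 1 library labelled MGMT above background. Astrocytic and neural stem cell markers held 8 higher, 5 lower and 8 not past of 21, and 14 passed when adjusted over the list alone (camera adjusted p = 0.558). The glutamate transporter SLC1A3 was higher by 5.25 (SE 0.555, adjusted p = 0.000669), and the lipid carrier APOE differed by -3.67 (SE 0.289, adjusted p = 0.000185). Neuronal markers held 9 higher, 3 lower and 6 not past of 18, and 12 passed when adjusted over the list alone (camera adjusted p = 0.103). GAP43, a growth cone protein, and GRIA3, a glutamate receptor subunit, were at least 18.6-fold and 12.6-fold higher.

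The TGF-beta and BMP pathway held 11 higher, 9 lower and 8 not past of 28 tested, and 20 passed when adjusted over the list alone (camera adjusted p = 0.941). BMP7, a bone morphogenetic protein, differed by -9.44 (SE 0.415, adjusted p = 1.68e-05), and GREM1, which binds and blocks such proteins, was at least 228-fold higher. Axon guidance molecules held 9 higher, 15 lower and 10 not past of 34, and 24 passed when adjusted over the list alone (camera adjusted p = 0.131). The netrin NTN1 differed by -7.91 (SE 0.428, adjusted p = 3.88e-05) on 1 probe, which was at background in all 3 libraries labelled MGMT. On its other probe, above background in 1 library labelled MGMT, NTN1 differed by -0.89. The semaphorin SEMA6D was at least 27.0-fold lower. Immediate early and serum response genes held 5 higher, 8 lower and 15 not past of 28, and 13 passed when adjusted over the list alone (camera adjusted p = 0.816). IER3, a stress-inducible survival gene, was higher by 5.22 (SE 0.253, adjusted p = 2.47e-05), and CCN1, a matricellular protein gene saturated on 2 arrays labelled empty vector, differed by -3.52 (SE 0.305, adjusted p = 0.000283).

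Markers of other cell types also moved in both directions, except that no epithelial marker was higher. Of 10 epithelial markers 5 were lower and 5 not past, and 5 passed when adjusted over the list alone (camera adjusted p = 0.0546). The keratin KRT18 differed by -8.28 (SE 0.259, adjusted p = 5.37e-06) and KRT8 by -1.35 (SE 0.182, adjusted p = 0.00189). Endothelial markers held 2 higher, 1 lower and 5 not past of 8, and 3 passed when adjusted over the list alone (camera adjusted p = 0.941). EGFL7 differed by -5.82 (SE 0.237, adjusted p = 1.25e-05) and PECAM1, an adhesion molecule of endothelium above background in 2 libraries labelled empty vector, by 4.53 (SE 0.753, adjusted p = 0.00441). Leukocyte markers held 3 higher, 2 lower and 5 not past of 10, and 5 passed when adjusted over the list alone (camera adjusted p = 0.713). The class II antigen presentation genes CD74 and HLA-DRA were higher by 6.22 (SE 0.359, adjusted p = 5.00e-05) and 5.04 (SE 0.846, adjusted p = 0.00456), CD74 being above background in 1 library labelled empty vector, and LAPTM5 differed by -4.75 (SE 0.612, adjusted p = 0.00156). Fibroblast and smooth muscle markers held 7 higher, 4 lower and 5 not past of 16, and 11 passed when adjusted over the list alone (camera adjusted p = 0.558). Besides COL1A1, LUM, the proteoglycan lumican, above background in 2 libraries labelled empty vector, was higher by 5.09 (SE 0.984, adjusted p = 0.00800), and THY1, a surface glycoprotein, differed by -4.48 (SE 0.488, adjusted p = 0.000764). With the slide as a block PECAM1, HLA-DRA and LUM did not pass (adjusted p = 0.0524, 0.0535 and 0.0949).

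Across the 30 lists, camera with its preset correlation called 7 (3 higher and 4 lower), and with an estimated correlation it called 0, against 3 at an unadjusted p under 0.05. By fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, 21 lists passed. For the receptor kinases, the VEGF and PDGF ligands, the integrins, the NF-kB targets, the proneural, immediate early and endothelial lists and the TGF-beta and BMP pathway, the median, the mean and the direction of the camera test did not all have the same sign. Without empty vector replicate 1 the medians of the DNA repair, proneural, TGF-beta, immediate early and leukocyte lists were negative. The epithelial list also passed with no scaling and with the slide as a block (adjusted p = 0.0471 and 0.0378), the neuronal list with spike-in scaling (adjusted p = 0.0361) and the NF-kB list with the filter on all 6 arrays (adjusted p = 0.0325).

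**Figure D4:**
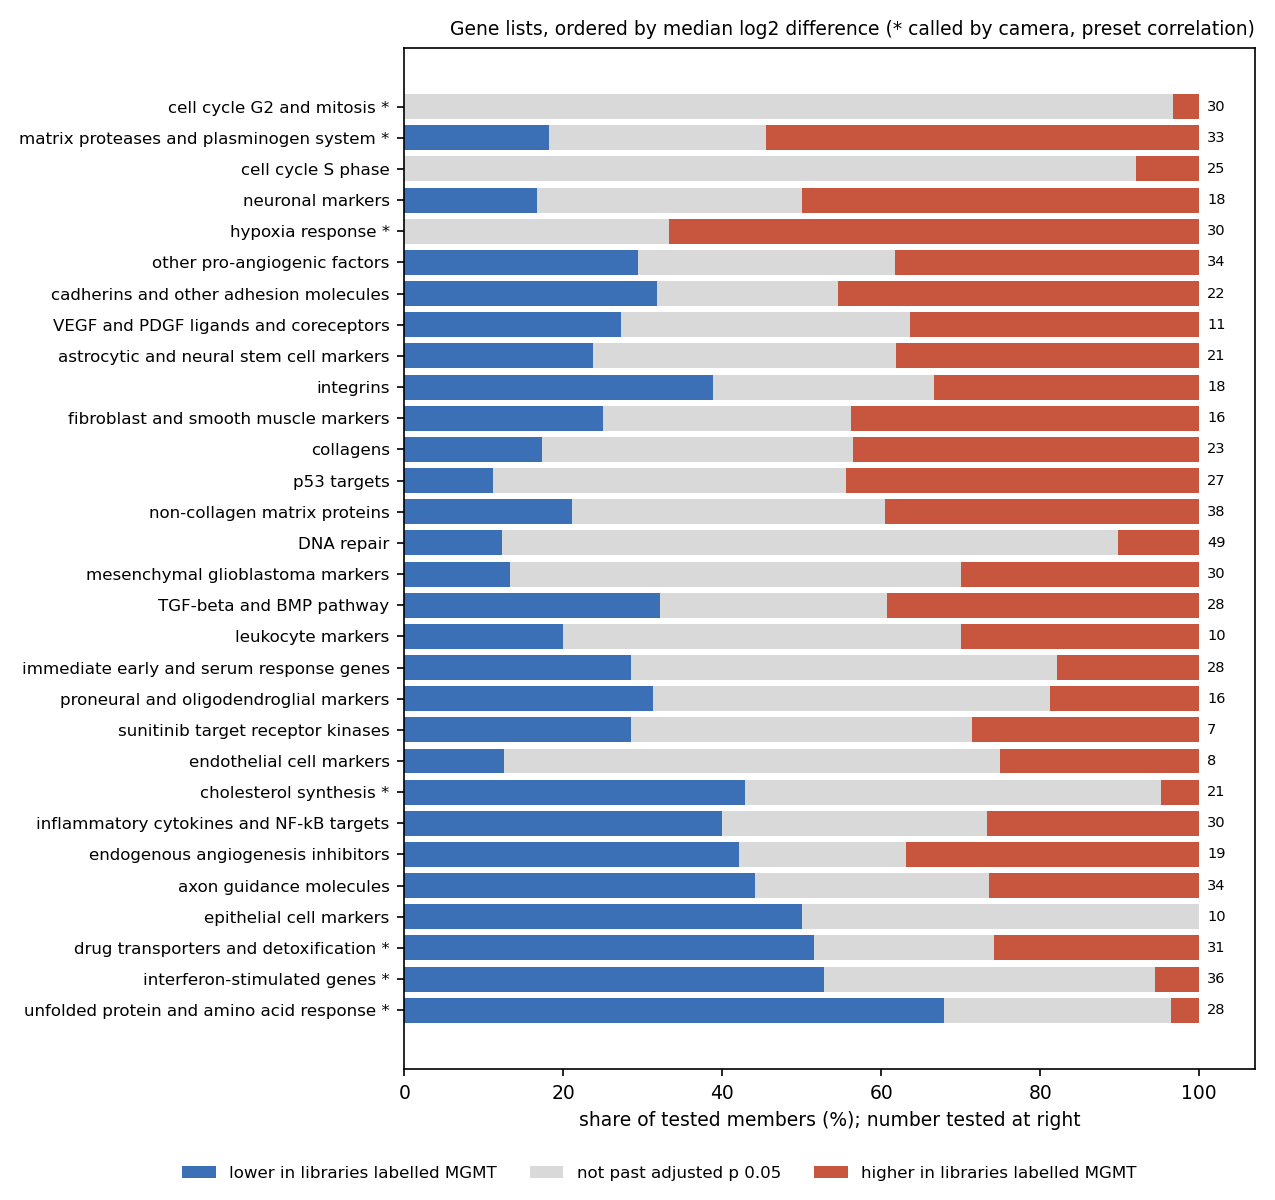
Share of the tested members of each gene list (x axis, percent, with the number tested at the right) that were lower, not past an adjusted p of 0.05, or higher in the libraries labelled MGMT, with the 7 lists called by camera at its preset correlation marked by an asterisk. Lists are ordered by their median difference, an order in which the medians of the DNA repair, mesenchymal and TGF-beta lists turn negative with spike-in scaling, which shifts every gene alike, and those of the proneural, immediate early and leukocyte lists turn under more than 1 scaling.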

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

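Spike-in scaling and the slide as a random block were chosen after the data were seen, and the other alternatives before. Of the values for named genes under alternatives, 2680 stayed on their side of the threshold, 174 no longer passed and 6 newly passed. For the gene lists these counts were 561, 18 and 20. No gene or list that passed in either setting changed direction. Among those that passed in neither, 5 values of genes (of FLT4 and ANGPT1) changed sign, and the direction of the camera test changed in 15 values of lists. The methods' t-test and the fit of each probe on its own were not run for the lists, and the threshold of 0.01 was run for gene counts only.

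The count of genes past the threshold, 8735 in the chosen settings, was 3923 with the slide as a block, 5159 at an adjusted p under 0.01 and 161 with the methods' t-test and Bonferroni correction. It ranged from 5643 without MGMT replicate 2 to 12148 without empty vector replicate 1, and was 11235 with the slide as a random block. The count past 2-fold, 6779 in the chosen settings, was 4339 with normexp background correction, 3923 with the slide as a block and 160 with the methods' t-test. By the methods' t-test, 9913 genes passed unadjusted and 7163 after Benjamini-Hochberg adjustment. A block on the slide leaves fewer arrays to compare, and Bonferroni correction and a threshold of 0.01 are stricter by construction. Normexp was run with an offset of 50, which is added to each signal and shrinks the log2 differences of dim genes by construction. How much of the lower count this accounts for was not tested. The replicate block gave 8766 and 7063 genes, and under this replicate block the drug transporter and cholesterol lists no longer passed (adjusted p = 0.0517 for each) while the S phase list did (adjusted p = 0.00147).

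The MGMT difference of -9.39 was lower in the libraries labelled MGMT under every alternative run, from -9.72 to -4.01. It did not pass with the methods' t-test and Bonferroni correction (-9.39, adjusted p = 0.0875). The share of higher genes fell to 32.4% with spike-in scaling, which moved the median of all genes by the same sign (-0.28). The number of lists called by camera was 0 with an estimated correlation. Signal over background limits genes that were dim in 1 group, whose folds are lower bounds.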

Other observations

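Of the tests below, those on the MGMT signal, on 9p21, on the HOX genes, on the slide and on neighbouring genes in their present form were chosen after the result was seen. HOX genes, which set position along the body axis, were not among the fixed lists and were chosen after their values were seen. Of 28 tested, 7 were higher, 13 lower and 8 not past, with 6 to 7 higher and 11 to 14 lower over the scalings tried. All 5 HOXC genes were lower (median -3.01), as were 4 of 7 HOXD genes (median -0.76), and no scaling turned these medians. HOXC13 was at least 152-fold lower (-9.43, SE 0.180, adjusted p = 2.40e-06) and HOXC10 at least 27.7-fold lower. The HOXA and HOXB clusters moved in both directions. HOXA4 was at least 349.6-fold higher (9.79, SE 0.495) and HOXA13 at least 58.6-fold lower, while HOXB2 was higher by 8.14 (SE 0.514) and HOXB9, above background in 1 library labelled MGMT, differed by -7.34 (SE 0.814).

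The MGMT signal was opposite to the label in 6 of the 6 arrays. An exchange of single arrays would leave fewer than 6 opposite, and an exchange of the slides would give MGMT replicate 3 the level of the arrays beside it, from which it differed by -8.96. An exchange of the labels of the whole groups, which needs 6 of 6, stays open as a hypothesis. MTAP, at least 113-fold apart, cannot weigh on it. Groups grown from 1 culture, with the 9p21 segment neither lost nor silenced since, would have MTAP alike whether or not the labels were exchanged. The MTAP difference argues only against such a shared, unaltered culture. U87 is known from textbook knowledge to lack the segment with CDKN2A, CDKN2B and MTAP, so a candidate explanation is that the libraries labelled empty vector do not come from the parent of the others, which no file here can settle. A probe that misses the transfected sequence also stays open: it would leave each group at its own level, and that level differed by at least 190-fold (189.8). None of the 3 reading frames of the 60-base probe held a stop, so the probe may lie in the coding sequence. If it does, a construct with the unaltered coding sequence would be detected. The sequence of the construct is not given.

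Neighbouring genes of 9p21 were at background in the libraries labelled MGMT. Among genes with a relative level above -3 in the libraries labelled empty vector, the longest run with every probe at background held 3 genes, KLHL9, LOC554202 and MTAP (permutation p = 0.0415 over 2000 shuffles of gene order). Without the minimum level it held 6 entries from KLHL9 on (permutation p = 5e-04, the smallest these shuffles can give). Entries were also merged within 10 kb or 50 kb, with the minimum level and without. With the minimum level the 3 genes above were the longest run in each setting (permutation p = 0.0185 to 0.0415). Without it, the longest runs lay in 4 places when merged within 10 kb (4 units, permutation p = 0.021) and in 5 places when merged within 50 kb (3 units, permutation p = 0.205), so these settings do not single out 9p21 and a chance run stays open. Low signal on 1 slide would spare MGMT replicate 3. On MGMT replicates 1 and 2 alone, the longest run of genes above -3 with the tested probe at background held 5 genes from MLLT3 to MTAP, and in MGMT replicate 3 their median was -8.52 relative to the arrays labelled empty vector on the same slide. A lost or silenced segment may remain as a hypothesis, against which CDKN2A, IFNA4, the other probe of FOCAD and 2 unnamed probes next to CDKN2B were above background in all 6 libraries, the unnamed ones with mean relative levels of 3.36 and 0.10 in the libraries labelled empty vector and 3.53 and 2.78 in those labelled MGMT.

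The difference between the groups was broad, with 6779 genes past 2-fold. If the slide were the cause, MGMT replicate 3 would be near the arrays labelled empty vector beside it. Genes were chosen on 4 arrays, MGMT replicates 1 and 2 and 2 labelled empty vector, and compared between MGMT replicate 3 and the empty vector array left out. The shares with the same sign and 2-fold size were 0.935 and 0.933 with empty vector replicates 2 and 3 left out, and 0.628 with replicate 1, which stands apart. The slide may still account for part of the genes, which a comparison with 1 array labelled MGMT cannot exclude. If brighter arrays were the cause, quantile normalization would lower the count, and it gave 1.01 times as many. A difference of parent culture, clone or culture condition may add to that of the transfected gene, and the design cannot tell these apart from the label.

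The 6 arrays allow 10 splits, too few for a share under 0.05. Each other split mixes the labels, so a broad difference between the labels enters its spread within groups and lowers its gene count. The ranking by gene count therefore cannot tell whether the grouping arose by chance. The real split was the 1 of 10 with the most genes (8735, highest other 0 by limma, and 1056 at an unadjusted p), the 1 of 10 with the most past 2-fold (6779, highest other 0), and one of 3 of 10 with as many lists (7, highest other 8). If the replicate numbers are taken as possible pairs, the 3 other splits that part all 3 numbers, as the real one does, gave at most 7 lists.

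Among genes at background in the libraries labelled empty vector, the length of the longest run of neighbours depended on how entries that lie close were counted. It held 4 entries with a minimum level of -3 (permutation p = 5e-04 over 2000 shuffles) and 2 units when entries within 50 kb were merged (permutation p = 0.648). The permutation p was 5e-04 to 0.01 in the 4 settings that kept entries apart or merged them within 10 kb. It was over 0.05 in the 2 settings that merged them within 50 kb, so the test does not decide. With the minimum level and merging within 10 kb, the longest run was NDN, SNURF, SNRPN and AL832758 (4 units, permutation p = 5e-04). It lay on chromosome 15, 21482148 to 22915975 on hg17. In that setting the run on 9p21 given above held 3 units (permutation p = 0.027). Over 272 windows of 10 Mb, the SD of the window medians was 0.346 against a median of 0.149 for shuffled positions (permutation p = 5e-04, the smallest that 2000 shuffles can give), and with entries within 50 kb merged it was 0.341 against 0.172 over 222 windows (permutation p = 5e-04). The window with the highest median lay on chromosome 13 (1.17, 71147823 to 79808682 on hg17), and 4 windows of chromosome 11 between 82120772 and 119864250 had medians of -0.749 or lower. Windows on chromosomes 1 (-0.96), 20 (-0.792) and 6 (-0.779) were below that value too.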
